A study of Mus musculus with 8 samples.

How the data were processed

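Gene expression was measured on 8 Affymetrix arrays, 1 for each combination of genotype, sorting marker and fraction. Keratinocytes came from the back skin of CD1 mice aged 8 weeks, either wild type or K14Snail, a transgenic line in which the transcription factor Snail is driven by the keratin 14 promoter. Per the labels' protocols, cells were selected magnetically with an antibody to CD34, a surface antigen of the hair follicle bulge, or to Mts24, an antigen carried by the Plet1 product in the upper follicle, and the positive and negative fractions were both profiled. Each CD34 array held a pool of 11 mice and each Mts24 array a pool of 9 mice, of mixed sex. Total RNA was amplified with a whole-transcript kit and labelled with biotin, per the labels' protocols.

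The deposited table holds log2 values per probe set, made by the authors with RMA, per the submitters' processing notes, a method that corrects background, normalizes between arrays and summarizes probes; its version is not given in the sources used here. The genome build is not given in the sources used here, and no coordinates were used. The log2 scale was read from the values, which run from 3.04 to 14.49 over the arrays. Array medians lay between 7.32 and 7.42 and no pair of arrays was identical. For arrays the number of arrays limits the precision, and here each group had 1 array.

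The table has 28874 probe sets. The platform annotation gives 21789 of them 1 gene symbol, 1621 several and 5464 none, and 21698 were matched by Entrez identifier to current gene names, with 0 symbols changed. Probe sets with several genes or none were left out of the comparisons. Where a gene had several probe sets (999 genes), the one with the highest mean over the 8 arrays was used, which left 19938 genes. A gene was tested when at least 2 of the 8 arrays reached 7.70, the median of all values of named genes, which kept 10720 genes. The arrays have no measure of background here, so where the arrays of a side lie under 7.70 the size and rank of a difference depend on the background and are uncertain. Close paralogues, such as those of the Stfa, Serpina3, Sprr and Trgv families, can share probe signal, so values of such genes are uncertain.

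Models were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 for tables and plots. One model held the 4 fractions and genotype, with the pool (genotype by marker) as a random block through duplicateCorrelation, whose consensus correlation was -0.175, and left 3 residual degrees of freedom with 2.78 prior degrees of freedom. It gave K14Snail against wild type averaged over the 4 fractions, CD34 positive against negative, Mts24 positive against negative, and the difference between these marker enrichments. A further term for genotype by positive or negative fraction gave the interaction, with 2 residual degrees of freedom and the same correlation. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and errors given with log2 differences are limma's moderated standard errors. The positive and negative fractions of a genotype and marker were taken to come from the same mice because their stated pool sizes match; the labels do not say so. With the negative correlation, errors of genotype differences are smaller than with no pool block. Genotype differences were compared over 4 pairs of arrays, which come from only 2 pools per genotype, and marker differences over 2 pairs, 1 per genotype. The p-values therefore measure the spread between these arrays, the disagreement between fractions included. A single fraction or genotype has 1 array per group and no replicate check: genes were counted at an absolute log2 difference of 1, and a list's median was placed among 10000 random lists of the same size matched on mean level.

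Before the data were examined, the models, 30 gene lists, the rule for named genes and most alternatives were fixed. The lists cover bulge stem cell, upper follicle, basal epidermis, suprabasal differentiation, wound-associated epidermis, sebaceous gland, hair shaft and inner root sheath, epithelial junction, epithelial to mesenchymal transition (EMT), cell cycle, p53 target, apoptosis inhibitor, DNA repair, immediate early, inflammatory cytokine, interferon response, Wnt target, Hedgehog pathway and Notch pathway genes, and markers of fibroblasts, endothelial cells, pericytes and smooth muscle, skeletal muscle, T cells, myeloid and Langerhans cells, neutrophils, mast cells, melanocytes, adipocytes and erythroid cells. The 23 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the 3 or 2 residual degrees of freedom of the model, so it could hardly call any list here. Its large adjusted p-values therefore do not show that a shift is absent or comes from correlation between genes. Several lists had estimated correlations far above 0.01, up to 0.95 for cell cycle genes. For such lists the p-values at the preset correlation are likely too small. Some listed genes, such as Cdkn1a, Isg15 and Flg, had no probe set with a single symbol and were not analysed here. Named genes are Snai1, Krt14, Cd34 and Plet1, the 10 largest and 10 smallest log2 differences among genes past the threshold with the same sign in all pairs, up to 4 members of each list with the largest absolute difference, and the 5 highest and 5 lowest genes of a single fraction. Where no gene passed, genes of the same sign in all pairs were ranked by their smallest pair difference. The largest changes given are those among the genes this rule names. Predicted genes, small RNA genes and olfactory receptors were counted but not named, and any other gene is said to have been chosen after its values were seen.

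The models were tested on simulated arrays for the 10720 genes with 200 genes changed. For the genotype comparison 81.9% of genes changed 1.5-fold, 94.4% changed 2-fold and 100% changed 4-fold were recovered, with 23 false among 206 calls; for CD34 the shares were 13.3%, 77.5% and 91.3%, with 6 false among 132 calls, and with no changed gene 0 calls were made in either. With a simulated correlation of 0 and no changed gene, 2 false genotype calls were made. The estimated pool correlation came out too low in these simulations: by interpolation, a true correlation of 0.0844 matched the observed estimate. At that value 26 of 198 simulated genotype calls were false (13.1%) with the estimated correlation and 8 of 174 with the true one. A fit with the correlation set to 0.0844 was therefore added, chosen after seeing the data. The simulations held no genotype difference particular to a fraction. In the real arrays the K14Snail minus wild type differences correlated across genes at 0.37 and 0.39 between the fractions of a marker. Between the 2 negative fractions this was 0.52, and between the 2 positive fractions 0.56. The simulations therefore do not fix the pool correlation of the real arrays. Other alternatives were a second quantile normalization, arrays shifted to the same median, no filter and a stricter filter, the mean of a gene's probe sets, a trended or robust prior, no pool block, the pool as a fixed block, pool means, and leaving out each pool; leaving out each array, and the list tests with arrays shifted to the same median, were added after seeing the data.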

Results

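The series compared sorted back-skin keratinocytes of K14Snail and wild type mice, in 8 groups of 1 array each: CD34 negative, CD34 positive, Mts24 negative and Mts24 positive cells of either genotype. The title places the study in stem and progenitor cells of K14Snail mice, and the design text names each negative fraction as the control of its positive fraction. Across genes, which are not independent replicates, wild type and K14Snail arrays of the same fraction correlated at r = 0.980 for CD34 negative, 0.938 for CD34 positive, 0.983 for Mts24 negative and 0.967 for Mts24 positive cells.

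Snai1 (probe set 10478884), the gene encoding Snail, was raised in every K14Snail array: its log2 level was 10.84 to 11.04 in the 4 K14Snail arrays and 7.86 to 8.16 in the 4 wild type arrays, a difference of 2.94 ± 0.06 (7.67-fold, adjusted p = 6.11e-05, higher in 4 of 4 pairs). The sources used here do not say which part of Snail the transgene carries, so whether the probe set separates transgene from endogenous transcripts is not known. Krt14 (probe set 10391052), whose promoter drives the transgene, was near the top of the scale in all arrays, between 13.28 and 13.80, with a genotype difference of 0.19 ± 0.06 that did not pass (adjusted p = 0.133). Cd34 (probe set 10352905) was higher in the CD34 positive than in the CD34 negative fraction by 7.24 ± 0.25 (adjusted p = 0.000203, 2 of 2 pairs) and in the Mts24 positive fraction by 1.57 ± 0.25 (2.98-fold, adjusted p = 0.0107). The CD34 negative arrays held Cd34 at 6.12 and 6.27, under the filter of 7.70, so the size of its CD34 difference depends on the background. The Mts24 negative arrays still held Cd34 at 10.03 in wild type and 10.51 in K14Snail. Plet1 (probe set 10585186), whose product carries the Mts24 antigen, rose by 3.22 ± 0.22 in the Mts24 positive fraction (9.33-fold, adjusted p = 0.00149), while its CD34 difference of 0.59 ± 0.22 did not pass (adjusted p = 0.111). Neither Cd34 (-0.05, adjusted p = 0.836) nor Plet1 (-0.25, adjusted p = 0.278) passed the genotype test.

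**Figure D1:**
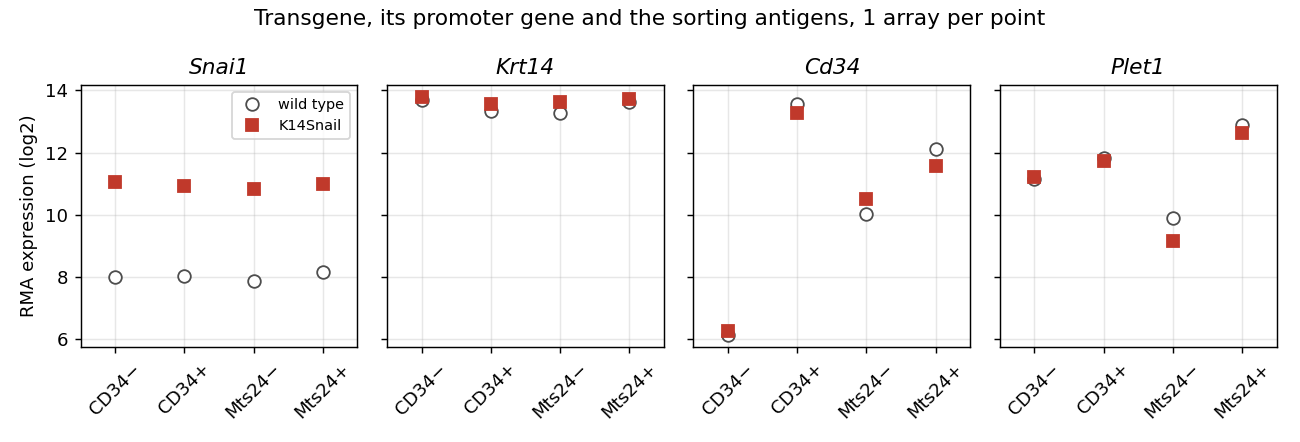
RMA log2 expression of Snai1, Krt14, Cd34 and Plet1 in each sorted fraction, with 1 point per array (open circles wild type, filled squares K14Snail). Snai1 lies between 10.84 and 11.04 in all K14Snail arrays and between 7.86 and 8.16 in wild type, and Cd34 rises from 6.12 to 13.57 across the wild type CD34 sort.

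K14Snail cells were compared with wild type cells over all 4 fractions to ask what the transgene changes in sorted keratinocytes. Besides Snai1, Bgn, which encodes the extracellular matrix proteoglycan biglycan, rose by 2.41 ± 0.16 (limma adjusted p = 0.0111). So did Sprr1b, a cornified envelope precursor (1.75 ± 0.10, 3.36-fold, adjusted p = 0.00535), and Aff2 (1.65 ± 0.05, adjusted p = 0.000543). These genes were each higher in 4 of 4 pairs. Aff2 was dim, under 7.70 in all wild type arrays and at most 7.91 in K14Snail. Among genes past the threshold Igfl3 rose most (3.01 ± 0.48, adjusted p = 0.0457). Also higher were Cxcl9, an interferon-induced chemokine (1.87 ± 0.22), the cysteine protease inhibitor Stfa3 (1.84 ± 0.26), the kallikrein Klk6 (1.81 ± 0.25), the chitinase-like Chil1 (1.75 ± 0.26) and the interferon-induced Rtp4 (1.51 ± 0.24). Among genes past the threshold the largest fall was in the serine protease inhibitor Serpina3b (-2.45 ± 0.40, adjusted p = 0.0487), followed by Efcab1 (-1.92 ± 0.21), Enpp5 (-1.88 ± 0.16), Adh6b (-1.61 ± 0.26) and Popdc3 (-1.50 ± 0.19). The cytochrome P450 gene Cyp2g1 had a larger difference, -3.78 ± 0.81, that did not pass (limma adjusted p = 0.0765). Serpina3b, Efcab1 and Cyp2g1 lay under 7.70 in all K14Snail arrays, so their sizes and ranks are uncertain. Lower as well were the noradrenaline transporter Slc6a2 (-1.42 ± 0.16), Zdhhc2 (-1.39 ± 0.16), the neuropeptide Y receptor Npy1r (-1.26 ± 0.13), Fgd4 (-1.23 ± 0.10) and Lrrc8b (-1.22 ± 0.11). In all, limma called 220 genes, 122 higher and 98 lower, of which 36 changed at least 2-fold. Across all tested genes 3383 (31.6%) had the same sign in all 4 pairs, where 12.5% would by chance if the pairs were independent. Pairs from the same pools need not be, so the share by chance is not known. The count depends on the pool correlation: it was 41 with no pool block, and 29 with a correlation of 0.0844, an alternative chosen after seeing the data. The negative correlation of the main fit makes genotype errors smaller: that of Bgn was 0.16, against 0.20 at 0.0844. Those 29 genes include Snai1, Bgn, Sprr1b, Aff2, Enpp5 and Fgd4 of those named here. Without 1 of the arrays it was 5 to 75. It was 20 without either CD34 pool, 0 without either Mts24 pool, and 1 with pool means and no marker term.

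Among the gene lists, 6 of 23 passed camera for genotype. Of the list members that passed singly for genotype, here and in the next paragraph, only Sprr1b also passed at the pool correlation of 0.0844. The list tests were not run at that value. Interferon response genes rose as a group (median 0.60, adjusted p = 6.75e-06, but adjusted p = 0.694 with an estimated correlation). Over all genes 4 of 11 rose, 0 fell and 7 did not pass, and adjusted over the list alone 9 rose. Rtp4, the antiviral genes Oasl2 (1.46 ± 0.20, adjusted p = 0.0376), the RNA sensor Ddx58 (0.89 ± 0.10, adjusted p = 0.0277) and Oas1a (0.60, adjusted p = 0.0435) passed, while the regulator Irf7 at 0.74 did not (adjusted p = 0.0511). Wound-associated epidermal genes were also higher (median 0.63, adjusted p = 0.000524; adjusted p = 0.694 with an estimated correlation). Over all genes 3 of 9 passed, Stfa3, Sprr1b and the hyperproliferation keratin Krt16 (1.46 ± 0.23, adjusted p = 0.0455), and 6 adjusted over the list alone. All 30 cell cycle genes had positive differences (median 0.55, camera adjusted p = 4.69e-07). With an estimated correlation, which was 0.95, camera's adjusted p was 0.816. None of the 30 genes passed singly: 0 did over all genes and 0 adjusted over the list alone. The shift lay mostly in CD34 positive cells, with medians of 0.01 in CD34 negative, 1.48 in CD34 positive, 0.39 in Mts24 negative and 0.36 in Mts24 positive cells. The mitotic checkpoint kinase Bub1 was at 1.07 ± 0.28, the spindle motor Kif11 at 1.01 ± 0.29, Top2a at 0.85 ± 0.32 and Cdk1 at 0.79 ± 0.26. Sebaceous gland genes were lower (median -0.35, adjusted p = 0.000309; adjusted p = 0.694 with an estimated correlation). Over all genes 0 of 15 passed, and 5 fell adjusted over the list alone. Sebaceous medians were -0.40 in CD34 negative, -1.27 in CD34 positive, -0.16 in Mts24 negative and -0.07 in Mts24 positive cells. The last lay inside the range of random lists, so the fall lay mostly in the CD34 arrays. The desaturase Scd3 was at -2.26 ± 0.51, the fatty acyl reductase Far2 at -2.17 ± 0.55, the elongase Elovl3 at -1.60 ± 0.48 and the melanocortin receptor Mc5r at -1.28 ± 0.35. Suprabasal differentiation genes were lower (median -0.26, adjusted p = 0.00876; adjusted p = 0.816 with an estimated correlation). Over all genes 0 of 20 passed and 0 adjusted over the list alone. The fall lay in the positive fractions, with medians of -1.31 in CD34 positive and -0.23 in Mts24 positive cells but 0.07 in CD34 negative and 0.12 in Mts24 negative cells. Loricrin (Lor) was at -0.65 ± 0.22. Epithelial junction genes were slightly lower (median -0.06, adjusted p = 0.00876; adjusted p = 0.694 with an estimated correlation). Over all genes 1 of 34 fell, the polarity gene Pard6b (-0.62 ± 0.06, adjusted p = 0.0246). Adjusted over the list alone 10 fell and 1 rose.

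EMT genes, a program that Snail is known to drive, did not pass as a group (median 0.30, camera adjusted p = 0.0790). Of 20 such genes on the array 13 were tested. Zeb1, Zeb2, Twist1 and Twist2 (named after their values were seen) did not pass the filter. By fraction the EMT medians were 0.25 in CD34 negative, 0.51 in Mts24 negative and 0.48 in Mts24 positive cells. These lay above the range of random lists, while the CD34 positive median was 0.005. Over all genes 1 of 13 rose, the matrix glycoprotein Tnc (0.90 ± 0.15, adjusted p = 0.0488). Adjusted over the list alone 3 rose and 1 fell. The related factor Snai2 stood at -1.83 ± 0.32 (adjusted p = 0.0549) and the matrix metalloproteinase Mmp2 at 1.25 ± 0.41 (adjusted p = 0.143), neither past the threshold. Bulge stem cell genes did not pass (median 0.07, adjusted p = 0.838; 1 of 21 rose, Tnc), nor did upper follicle genes (0.24, adjusted p = 0.0914; 5 rose adjusted over the list alone). The same held for basal epidermis (0.02, adjusted p = 0.959), hair shaft and inner root sheath (0.01, adjusted p = 0.981, with the test leaning to lower), p53 targets (0.06, adjusted p = 0.157), and apoptosis inhibitors (0.05, adjusted p = 0.862). Nor did a shift pass for DNA repair (0.06, adjusted p = 0.451), immediate early genes (0.10, adjusted p = 0.454) or inflammatory cytokines (0.04, adjusted p = 0.454; the monocyte chemokine Ccl2 rose by 1.47 ± 0.20). Signalling lists did not pass either, with Wnt targets (-0.10, adjusted p = 0.201) beside Hedgehog (0.10, adjusted p = 0.931, with a mean of -0.01 and the test leaning to lower) and Notch pathway genes (-0.02, adjusted p = 0.485). Of the lists for other cell types, myeloid and Langerhans cell genes had a median of 0.43 (adjusted p = 0.0914) and melanocyte genes 0.46 (adjusted p = 0.453). T cell genes had -0.09 (adjusted p = 0.128) and fibroblast genes 0.10 (adjusted p = 0.595; Fbln2 rose by 0.46 ± 0.07).

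Within single fractions, with 1 array per group and no test, the K14Snail and wild type arrays differed by at least 2-fold at 530 genes in CD34 positive cells, 205 in Mts24 positive, 92 in CD34 negative and 79 in Mts24 negative cells. Cyp2g1 was the lowest gene in 3 fractions, at -5.07 in CD34 negative, -5.63 in CD34 positive and -4.08 in Mts24 negative cells. Among the other lowest genes Fa2h was at -3.34 and -3.68 and Far2 at -3.32 and -3.57 in the CD34 negative and positive pairs. Hsd3b6 (-3.03) and Efcab1 (-2.89) followed in the CD34 negative pair, and Scd3 (-4.13) and Serpina3b (-3.96) in the CD34 positive pair. In CD34 positive cells the highest genes after Igfl3 (4.19) were the macrophage lysozyme Lyz2 (3.32), smooth muscle actin Acta2 (2.89) and Snai1 (2.89). In Mts24 positive cells they were Lyz2 (3.22), Rnase2b (3.18) and Stfa3 (2.85), with Ifitm6 (-2.68) and Scgb1a1 (-2.40) lowest. Lyz2 lay under 7.70 in all wild type arrays, so its size and rank are uncertain. In CD34 negative cells Igfl3 (4.02), Snai1 (3.05), Klk6 (2.68), Hmcn1 (2.58) and Mmp2 (2.42) stood highest. In Mts24 negative cells the highest were Pyy (3.10), Snai1 (2.98), Bgn (2.26) and Mmp2 (2.19), and Snai2 was at -2.86. The cell cycle median in CD34 positive cells lay above all 10000 random lists. Myeloid genes were higher in both positive fractions: their median was 1.25 in CD34 positive and 1.24 in Mts24 positive cells but -0.49 and -0.06 in the matching negative fractions. Suprabasal genes (-1.31) and sebaceous genes (-1.27) were lowest in the CD34 positive pair. Y-linked transcripts also differed between pools of mixed sex: Eif2s3y was higher in K14Snail by 0.94 in CD34 negative, 0.46 in CD34 positive, 0.50 in Mts24 negative and 0.30 in Mts24 positive cells, and Uty by 1.08, 0.66, 0.45 and 0.36 in the same order. Kdm5d was lower in Mts24 negative cells (-0.21) and higher in the others, and Xist differed by 0.02 on average. The sources used here do not give the sex ratio of each pool, so effects of sex ratio cannot be told apart from those of genotype.

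**Figure D2:**
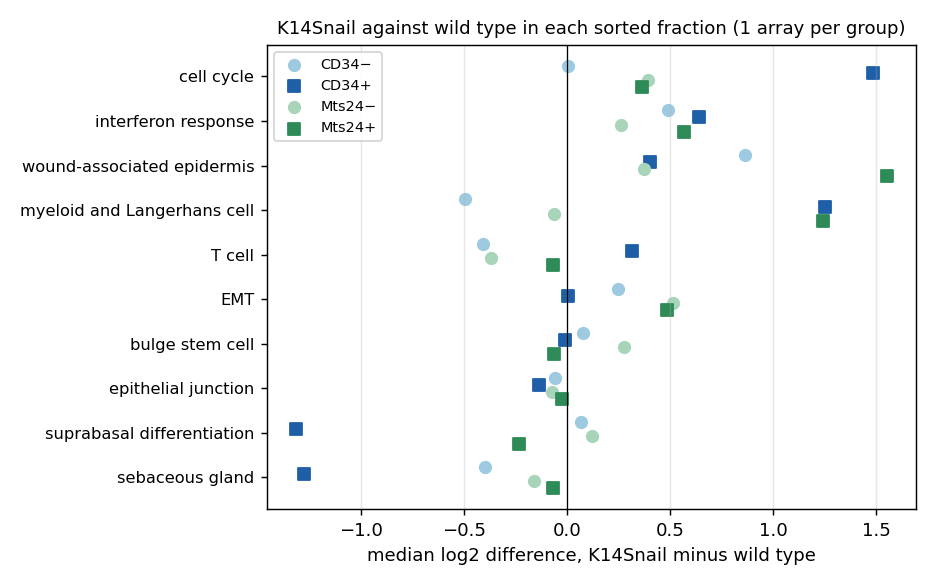
Median log2 difference between the K14Snail and wild type arrays (x axis) of 10 gene lists (y axis) in each sorted fraction, with 1 array per group. Cell cycle genes reach 1.48 in CD34 positive cells and lie at 0.01 in CD34 negative cells, and myeloid genes lie at 1.25 and 1.24 in the positive fractions and at -0.49 and -0.06 in the negative ones.

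The interaction asked whether the positive and negative fractions differ by another amount in K14Snail than in wild type cells. Myeloid and Langerhans cell genes had the largest list shift, with a median of 1.30 and 13 of 13 positive (camera adjusted p = 1.66e-17). With an estimated correlation, which was 0.39, camera's adjusted p was 0.668. Over all genes 0 passed, and 12 rose adjusted over the list alone. Lyz2 was at 2.93 ± 0.18, the class II invariant chain Cd74 at 2.22 ± 0.24, H2-Ab1 at 2.18 ± 0.40 and H2-Aa at 1.81 ± 0.28, and none passed. The intermediate filament gene Vim (1.80 ± 0.14), the leukocyte genes Laptm5 (1.72) and Cd53 (1.90), and Lcn2 (1.97) stood high, and Serpina12 (-1.87), Ifitm6 (-2.41), Mrgprb3 (-2.36) and Car6 (-1.95) low, again without passing. Cell cycle genes had a median of 0.80 (adjusted p = 7.13e-07, but adjusted p = 0.668 with an estimated correlation). This came from the CD34 sort, where the positive minus negative median was -0.88 in wild type and 0.70 in K14Snail, against 1.13 and 1.15 in the Mts24 sort. For the lists that follow, too, adjusted p = 0.668 with an estimated correlation. T cell and interferon response genes had 0.30 and 0.29 (adjusted p = 0.0196 each). Suprabasal genes had -0.71 (adjusted p = 2.05e-11; Flg2 -1.15 ± 0.17) and basal epidermis genes -0.30 (adjusted p = 2.36e-06; Thbs1 -0.89 ± 0.13). Immediate early genes had -0.27 (adjusted p = 0.00329), fibroblast genes -0.19 (adjusted p = 0.0196) and bulge genes -0.10 (adjusted p = 0.000650). For bulge genes the medians were alike in the CD34 sort (2.44 in wild type, 2.43 in K14Snail) and lower in K14Snail in the Mts24 sort (1.47 and 1.12). In each of these lists 0 members passed over all genes. Adjusted over the list alone 3 basal, 2 fibroblast and 1 suprabasal genes were lower, and 0 genes of the cell cycle, T cell, interferon, immediate early and bulge lists passed. With limma 0 genes passed singly, while 845 had an unadjusted p under 0.05, where 536 would by chance, and the smallest adjusted p was 0.118. With the pool correlation of 0.0844 4 genes passed, Laptm5, Lyz2, Vim and Serpina12 (adjusted p = 0.0492 each), and with no pool block or another normalization, filter or prior 0 did.

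CD34 positive cells were compared with CD34 negative cells, with the genotypes as replicates, to describe the bulge fraction. All 21 bulge stem cell genes rose (median 2.38, camera adjusted p = 3.42e-19; adjusted p = 0.402 with an estimated correlation), and 21 also did adjusted over the list alone. Cd34 itself is on the list and was used for the sort. The largest were the stem cell receptor Lgr5 (5.33 ± 0.26, adjusted p = 0.000283), the transcription factor Lhx2 (4.70 ± 0.24, 26.0-fold) and the growth factor Fgf18 (4.27 ± 0.37). Outside the list the largest rises were in the small proteoglycan Aspn (6.57 ± 0.43, adjusted p = 0.000536), Angptl7 (5.81 ± 0.21), Serpinb11 (5.69 ± 0.52) and the cytokine receptor Il31ra (5.48 ± 0.30). Aspn lay at 5.49 and 4.97 in the CD34 negative arrays, under the filter, so its size and rank are uncertain. Then came the endocytic adaptor Dab2 (5.08 ± 0.25), the BMP antagonist Grem1 (5.02 ± 0.41) and Pdzrn4 (4.81 ± 0.26). The largest falls were in the cytokine receptor Il20ra (-3.94 ± 0.43, adjusted p = 0.00249), the protease Tmprss11g (-3.43 ± 0.37), the chemokine receptor Ccr4 (-3.36 ± 0.43) and the potassium channel Kcnj16 (-3.25 ± 0.19). Next were Sema3d (-3.22), the chromatin organizer Satb1 (-3.20), Slc24a3 (-3.08), Bmp4 (-3.04 ± 0.34), Npy1r (-3.02) and Npl (-3.01). In all 2542 genes passed, 1298 higher and 1244 lower, 981 of them by at least 2-fold. Within single genotypes, 1124 genes differed by at least 2-fold in wild type and 1192 in K14Snail.

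Of the 10 lists that passed for CD34, Hedgehog pathway genes were higher (median 1.48, adjusted p = 0.000285; adjusted p = 0.402 with an estimated correlation). Of these 5 of 6 rose, both over all genes and adjusted over the list alone. The Hedgehog-binding Hhip stood at 2.66 ± 0.23, Gli2 at 2.07 ± 0.12, Gli1 at 1.67 ± 0.25 and Gli3 at 1.30 ± 0.20. EMT genes were higher (median 1.52, adjusted p = 0.00246; adjusted p = 0.402 with an estimated correlation). Over all genes 6 of 13 were higher and 6 adjusted over the list alone, among them S100a4 (2.90 ± 0.22), Tnc (2.62 ± 0.25, also a bulge list gene), Cdh11 (2.43 ± 0.24) and Sparc (1.65 ± 0.18). Fibroblast genes were higher (median 0.90, adjusted p = 0.0202; adjusted p = 0.514 with an estimated correlation). Over all genes 5 of 8 rose, led by Fbln1 (2.71 ± 0.20), Col6a2 (1.83 ± 0.15) and Col6a1 (1.78 ± 0.30). Only 8 of the 17 listed fibroblast genes were tested. The others, such as Dcn, Lum and Pdgfra (named after their values were seen), did not pass the filter. The T cell and fibroblast gene Thy1 (-1.98 ± 0.09) was the 1 that fell, and the counts were the same adjusted over the list alone. T cell genes were lower (median -1.95, adjusted p = 6.60e-05; adjusted p = 0.402 with an estimated correlation). Over all genes 7 of 9 were lower and 8 adjusted over the list alone, such as the receptor chain Cd3g (-2.40 ± 0.28), Trat1 (-2.31 ± 0.38) and Cd7 (-2.04 ± 0.32). Myeloid genes were lower (median -0.98, adjusted p = 0.0439; adjusted p = 0.839 with an estimated correlation). Over all genes 2 of 13 fell, Ptprc (-1.90 ± 0.40) and Fcer1g (-1.61 ± 0.31), also 2 adjusted over the list alone. The genotypes differed, with a median of -1.99 in wild type and -0.04 in K14Snail, the latter inside the range of random lists. Suprabasal genes were lower (median -0.85, adjusted p = 0.0158; adjusted p = 0.839 with an estimated correlation). Over all genes 3 of 20 were lower, among them Krt1 (-1.85 ± 0.44) and Calm4 (-1.77 ± 0.47), and 0 adjusted over the list alone. The fall lay mostly in K14Snail, with a median of -1.40 and 0 of 20 genes above 0. In wild type the median was -0.28, with 7 of 20 above 0. Junction genes were lower (median -0.21, adjusted p = 0.0187; adjusted p = 0.402 with an estimated correlation). Over all genes 10 of 34 fell and 3 rose, and 12 and 3 did adjusted over the list alone. They include the epithelial regulators Ovol1 (-1.29 ± 0.19) and Esrp2 (-0.99 ± 0.15) and the tight junction gene Tjp3 (-1.27 ± 0.21). Immediate early genes (median -0.60, adjusted p = 0.0234; adjusted p = 0.839 with an estimated correlation) had 5 of 16 lower, such as Fos (-1.29 ± 0.27) and Junb (-0.93 ± 0.22). Ier3 (1.49 ± 0.12) was the 1 higher, with the same counts adjusted over the list alone. Inflammatory cytokine genes (median -0.70, adjusted p = 0.0357; adjusted p = 0.402 with an estimated correlation) had 2 of 9 lower, Il33 (-2.40 ± 0.22) and Il1rn (-1.88 ± 0.14), again 2 adjusted over the list alone. Without the wild type or the K14Snail CD34 negative array the count of genes was 1200 or 1154, and without either Mts24 pool, which then leaves the spread to be estimated from fewer arrays, it was 1422.

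Mts24 positive cells were compared with Mts24 negative cells in the same way, to describe the upper follicle fraction. All 10 upper follicle genes rose (median 1.72, adjusted p = 2.80e-07; adjusted p = 0.558 with an estimated correlation), and all 10 did adjusted over the list alone, Plet1 among them. The transcription factor Gata6 rose by 3.81 ± 0.25 (14.0-fold, adjusted p = 0.00149), the defensin Defb6 by 2.63 ± 0.20 and the stem cell regulator Lrig1 by 2.17 ± 0.32. The largest rises overall were in Calhm5 (4.60 ± 0.33, adjusted p = 0.00177), the gasdermin Gsdma3 (4.58 ± 0.20), the cornified envelope gene Sprr4 (4.47 ± 0.43) and Igfl3 (4.19 ± 0.80). Next were Serpinb11 (3.60), Aspn (3.55), Aadac (3.39), the integrin Itgb8 (3.39) and Vsnl1 (3.34). Most of the largest falls were in lymphocyte genes, led by the cytotoxic granule gene Nkg7 (-4.25 ± 0.28, adjusted p = 0.00149) and Cd3g (-4.16 ± 0.28). Next were Kir3dl2 (-3.73), the gamma chain segment Trgv1 (-3.65), Cd7 (-3.64), Cd3e (-3.64), Trat1 (-3.54), Srgn (-3.50), the epidermal lipoxygenase Alox12 (-3.30) and Cd96 (-3.13). In all 2448 genes passed, 1195 higher and 1253 lower, 765 of them by at least 2-fold. Within single genotypes 916 genes differed by at least 2-fold in wild type and 1000 in K14Snail.

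Of the 11 lists that passed for Mts24, bulge genes were higher (median 1.39, adjusted p = 3.19e-10; adjusted p = 0.558 with an estimated correlation). Over all genes 15 of 21 rose, 18 adjusted over the list alone, led by Fst (3.29 ± 0.13), Foxc1 (3.12 ± 0.09), Cd200 (3.04 ± 0.09) and Sox9 (2.40 ± 0.09). Cell cycle genes were higher (median 1.14, adjusted p = 5.53e-07; adjusted p = 0.617 with an estimated correlation). Over all genes 9 of 30 passed and 25 adjusted over the list alone. The largest, Ccna2 (1.71 ± 0.55) and Cdk1 (1.58 ± 0.44), did not pass over all genes. DNA repair genes were higher (median 0.27, adjusted p = 0.0307; adjusted p = 0.558 with an estimated correlation). Over all genes 5 of 17 were higher and 7 adjusted over the list alone, such as Chek1 (1.45 ± 0.29) and Exo1 (1.09 ± 0.27). Wound-associated genes were higher (median 1.34, adjusted p = 0.00330; adjusted p = 0.558 with an estimated correlation). Over all genes 6 of 9 were higher and 7 adjusted over the list alone, with the keratins Krt6a at 3.04 ± 0.45 and Krt16 at 1.59 ± 0.39. Basal epidermis genes (median 0.32, adjusted p = 0.0148; adjusted p = 0.617 with an estimated correlation) had 4 of 14 up, such as Lamb3 (0.81 ± 0.22) and Itgb1 (0.74 ± 0.15). Hedgehog genes (median 0.54, adjusted p = 0.0427; adjusted p = 0.592 with an estimated correlation) had 2 of 6 higher, Gli3 (1.60 ± 0.20) and Smo (0.64 ± 0.11). Adjusted over the list alone 4 rose in each. Basal medians were 0.56 in wild type and 0.10 in K14Snail, and Hedgehog medians 0.71 and 0.27. Both K14Snail medians lay inside the range of random lists. T cell genes were lower (median -2.23, adjusted p = 3.52e-06; adjusted p = 0.558 with an estimated correlation). Over all genes 8 of 9 were lower and Cd5 up (0.64), the same counts adjusted over the list alone. Myeloid genes were lower too (median -1.20, adjusted p = 0.00164; adjusted p = 0.617 with an estimated correlation). Over all genes 4 of 13 were lower, such as Ptprc (-2.69 ± 0.40) and Fcer1g (-2.50 ± 0.31), and 8 adjusted over the list alone. The median was -2.16 in wild type and -0.71 in K14Snail. Suprabasal genes were lower (median -0.64, adjusted p = 0.00430; adjusted p = 0.693 with an estimated correlation) with 0 of 20 past the threshold and 0 adjusted over the list alone. Junction genes (median -0.12, adjusted p = 0.0477; adjusted p = 0.558 with an estimated correlation) had 9 of 34 down and 3 up, 11 and 3 adjusted over the list alone, such as Tjp3 (-1.14 ± 0.21) and, higher, Epcam (0.77 ± 0.11). The count of genes was 0 without either Mts24 pool, and 808, 979, 661 and 987 without the wild type Mts24 negative or positive or the K14Snail Mts24 negative or positive array.

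**Figure D3:**
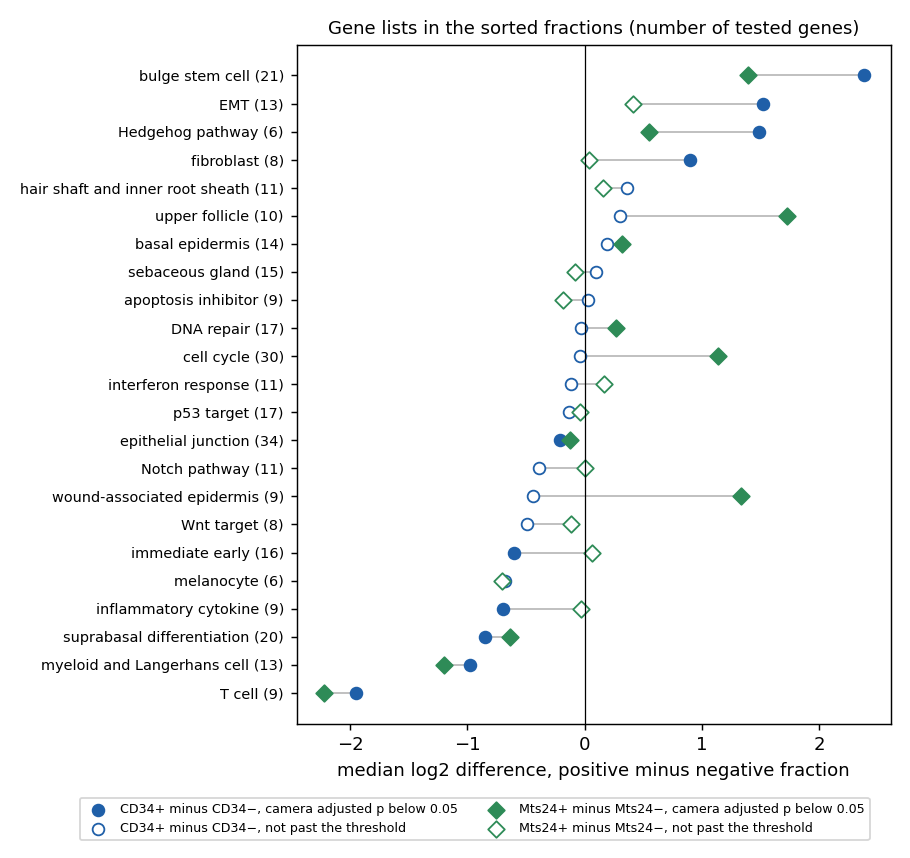
Median log2 difference between the positive and negative fraction (x axis) of the 23 tested lists (y axis, number of tested genes in parentheses), circles for CD34 and diamonds for Mts24, filled where the camera adjusted p is below 0.05. Bulge genes lie at 2.38 for CD34 and 1.39 for Mts24, upper follicle genes at 1.72 for Mts24, and T cell genes at -1.95 and -2.23.

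The difference between the CD34 and Mts24 enrichments asked which genes separate the bulge fraction from the upper follicle fraction. On the CD34 side stood Cd34 (5.66 ± 0.35), Il31ra (4.42 ± 0.43), Lgr5 (4.36 ± 0.37, adjusted p = 0.00883) and Angptl7 (4.19 ± 0.30). They were followed by Scrg1 (3.90 ± 0.35), Dab2 (3.61), Pdzrn4 (3.59), Grem1 (3.51), Fstl1 (3.27) and Tmtc1 (3.24). On the Mts24 side stood Sprr4 (-5.91 ± 0.61, adjusted p = 0.0113), Gata6 (-3.44 ± 0.36) and Aadac (-3.37). They were followed by the kallikrein Klk10 (-3.20), the organic anion transporter Slco2b1 (-3.17), Sox7 (-2.91), Mab21l4 (-2.90), Calhm5 (-2.85), Gsdma3 (-2.81) and Abi3bp (-2.77). Genes past the threshold in both sorts mostly ran the same way: 639 were higher in both (145 for independent lists) and 730 lower in both (145). Another 12 were higher for CD34 and lower for Mts24 (152) and 29 the reverse (139). The sorts share no arrays, but they share an estimate of the spread and a genotype term.

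Bulge genes lay on the CD34 side (median 1.23, adjusted p = 1.56e-07, but adjusted p = 0.388 with an estimated correlation). Of these genes 9 of 21 were higher and 3 lower, and 14 and 3 adjusted over the list alone, with Lhx2 at 3.06 ± 0.34 and Igfbp5 at 2.63 ± 0.16. EMT genes lay on that side too (median 0.90, adjusted p = 0.00459, but adjusted p = 0.388 with an estimated correlation). Of these genes 2 of 13 were higher, and 4 adjusted over the list alone, with S100a4 at 2.76 ± 0.31. Fibroblast genes lay there as well (median 0.80, adjusted p = 0.00459, but adjusted p = 0.4001 with an estimated correlation). Of these genes 3 of 8 were higher and 1 lower, and 4 and 1 adjusted over the list alone, with Fbln1 at 2.00 ± 0.28. Hedgehog genes followed (median 1.27, adjusted p = 0.0169, but adjusted p = 0.440 with an estimated correlation). Of these genes 2 of 6 were higher, and 4 adjusted over the list alone, with Gli2 at 1.62 ± 0.18. Melanocyte genes did as well (median 1.05, adjusted p = 0.0136, but adjusted p = 0.388 with an estimated correlation). Of these genes 1 of 6 was higher, Mitf (1.68 ± 0.20), and 2 adjusted over the list alone. The melanocyte median was below 0 in both sorts, at -0.68 for CD34 and -0.70 for Mts24. In wild type it was -0.95 for CD34 and -0.48 for Mts24, and in K14Snail -0.27 and -1.04. The genotypes thus ran opposite ways between the sorts. Hair shaft genes were the last on the CD34 side (median 0.53, adjusted p = 0.0352, but adjusted p = 0.388 with an estimated correlation). Of these genes 2 of 11 were higher, Hoxc13 (1.65 ± 0.29) and S100a3 (1.19 ± 0.16), and 2 adjusted over the list alone. Upper follicle genes lay on the Mts24 side (median -1.63, adjusted p = 4.29e-08, but adjusted p = 0.388 with an estimated correlation). Of these genes 4 of 10 passed, and 8 adjusted over the list alone, with Defb6 at -2.62 ± 0.28. Cell cycle genes lay there too (median -1.27, adjusted p = 3.93e-08, but adjusted p = 0.477 with an estimated correlation). Of these genes 0 of 30 passed, and 0 adjusted over the list alone, with Mki67 at -1.84 ± 0.87. In wild type the cell cycle medians were -0.88 for CD34 and 1.13 for Mts24, against 0.70 and 1.15 in K14Snail. Wound-associated genes followed (median -1.49, adjusted p = 0.00205, but adjusted p = 0.388 with an estimated correlation). Of these genes 1 of 9 passed, Sprr1b (-2.54 ± 0.23), and 4 adjusted over the list alone. Immediate early genes did as well (median -0.83, adjusted p = 0.00173, but adjusted p = 0.477 with an estimated correlation). Of these genes 1 of 16 passed, Egr2 (-2.34 ± 0.25), and 1 adjusted over the list alone. Inflammatory cytokines were likewise lower (median -0.79, adjusted p = 0.00269, but adjusted p = 0.388 with an estimated correlation). Of these genes 3 of 9 passed, and 4 adjusted over the list alone, with Ccl2 at -2.67 ± 0.48 and Il33 at -2.37 ± 0.32. DNA repair genes had the smallest shift (median -0.20, adjusted p = 0.0236, but adjusted p = 0.440 with an estimated correlation). Of these genes 0 of 17 passed, and 0 adjusted over the list alone, with Chek1 at -1.72 ± 0.40. In all 437 genes passed, 255 on the CD34 side and 182 on the Mts24 side. The count was 232 with the pool as a fixed block, 744 without the K14Snail CD34 pool, 0 without either Mts24 pool, and 14 to 830 without single arrays.

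**Figure D4:**
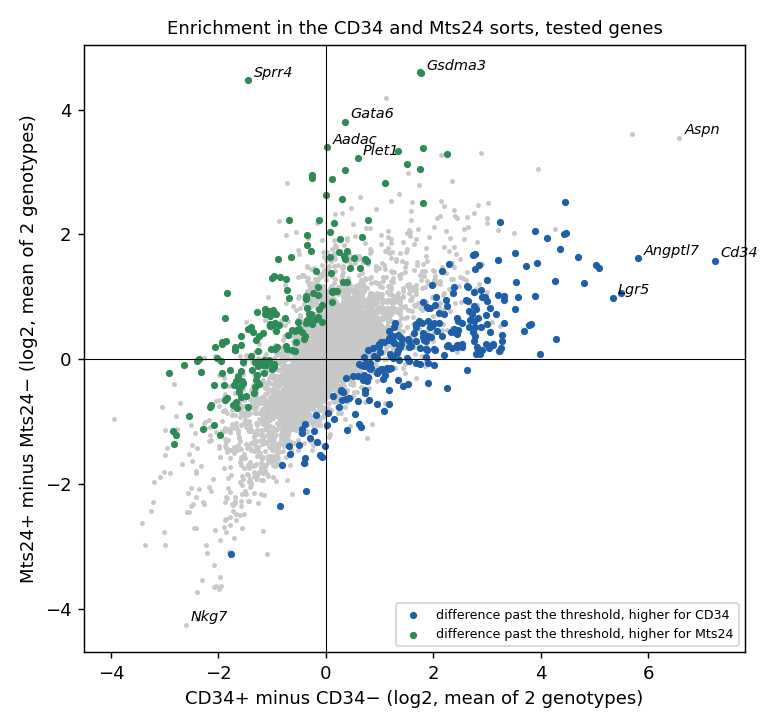
Log2 enrichment of each tested gene in the CD34 sort (x axis) against the Mts24 sort (y axis), each the mean of both genotypes; grey points are genes whose difference between sorts did not pass, and coloured points the 437 that did. Cd34 lies at 7.24 on the x axis and Gata6 at 3.81 on the y axis.

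Markers of cells that sorted skin could hold besides keratinocytes were mostly dim. Of the 14 endothelial genes 0 were tested, with array medians of 6.58 to 6.85, under the filter of 7.70. The erythroid list also had 0 tested genes (medians 6.76 to 7.02). The other small lists had no list test: pericyte and smooth muscle medians lay between 6.64 and 6.81 with 3 tested genes (Acta2 differed by 1.11 ± 0.41 between genotypes, adjusted p = 0.167), skeletal muscle between 6.83 and 7.30 with 2, neutrophil between 5.37 and 5.55 with 2, adipocyte between 6.61 and 6.96 with 2, and mast cell between 5.38 and 5.85 with 1. Fibroblast medians lay between 7.34 and 7.64, also under the filter, with 8 of 17 genes tested. T cell medians ranged from 8.01 to 8.66 in negative fractions and from 6.54 to 6.94 in positive fractions, and myeloid medians from 8.03 to 8.51 and from 6.81 to 7.70.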

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

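All tests of explanations given here were chosen only after the results they concern were seen.

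Some differences between groups passed a test of the difference itself. Between genotypes, the positive minus negative difference shifted for 9 lists with camera's preset correlation, and for 0 with an estimated one (adjusted p = 0.668 each). They had medians of 1.30 for myeloid and Langerhans cell, 0.80 for cell cycle, 0.30 for T cell, 0.29 for interferon response, -0.10 for bulge, -0.19 for fibroblast, -0.27 for immediate early, -0.30 for basal epidermis and -0.71 for suprabasal genes, while 0 single genes passed (limma; 845 at an unadjusted p under 0.05). The cell cycle shift came from the CD34 sort, since in the Mts24 sort the medians were 1.13 in wild type and 1.15 in K14Snail. Between the sorts, 437 genes and 12 lists differed, with medians of 1.27 for Hedgehog, 1.23 for bulge, 1.05 for melanocyte, 0.90 for EMT, 0.80 for fibroblast and 0.53 for hair shaft genes on the CD34 side, and -1.63 for upper follicle, -1.49 for wound-associated, -1.27 for cell cycle, -0.83 for immediate early, -0.79 for inflammatory cytokine and -0.20 for DNA repair genes on the Mts24 side. None of these 12 lists passed with an estimated correlation, a setting where few residual degrees of freedom hardly allow a call. Among probe sets with no gene or several genes, which entered no comparison, 16 passed for genotype, 201 for CD34, 254 for Mts24 and 15 for the difference between sorts.

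Myeloid transcripts were higher in both K14Snail positive fractions than in the wild type ones. Carry-over of negative cells would bring T cell transcripts along, but over both positive fractions the myeloid median exceeded the T cell median by 1.08 (13 against 9 genes, permutation p = 0.00044 over genes, which are not independent replicates). In CD34 positive cells the T cell median was 0.31, so carry-over of part of the rise stays open there, while in Mts24 positive cells it was -0.07. Lyz2, the most raised, was at 8.97 in the K14Snail CD34 positive array and 6.04 in its negative fraction. A rise of Cd74 and the class II genes in keratinocytes alone is argued against by the 9 other myeloid genes, whose medians were 1.09 in CD34 positive and 0.72 in Mts24 positive cells. Nonspecific capture of myeloid cells by antibody or beads stays open, since the median rise in the sorts differed by 0.00598. More myeloid cells close to K14Snail follicles, or myeloid genes expressed by other cells, could give the same values and were not tested; the sort does not remove myeloid cells that bind the antibody.

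Cell cycle transcripts were higher in the K14Snail CD34 positive array than in the wild type one, by a median of 1.48. In the same arrays suprabasal genes were at -1.31, sebaceous genes at -1.27, myeloid genes at 1.25, melanocyte genes at 0.66 and upper follicle genes at 0.61, so the mix of cells may differ. Carry-over of CD34 negative cells is argued against by a median 0.70 higher than in the K14Snail CD34 negative array, with 30 of 30 genes higher; in wild type the same median was -0.88. Other array scalings left the median at 1.47 or more. The wild type and K14Snail CD34 positive arrays already had medians of 7.388 and 7.389, so these scalings could hardly move it and do not decide on scaling. A loss of bulge cells from the fraction stays open: the bulge genes had a median of -0.0123 but went both ways, with 9 of 21 above 0. More cycling bulge cells or another hair cycle stage in the K14Snail pool may give these values; neither was tested, and this rests on 1 array per genotype.

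The 220 genes that passed for genotype were set against the other ways to exchange genotype labels within fractions. These exchange single fractions and so ignore that fractions of a pool are taken to share mice. The 8 splits are too few for a share under 0.05; the real split gave 220 and the highest other 0.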

How the results depend on the processing

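Leaving out single arrays and the fit with a pool correlation of 0.0844 were chosen after seeing the data, as was the shift to the same median for lists; the other alternatives were not. The genotype count of 220 was 175 to 282 over other scalings, filters, probe summaries, priors and pool means with the marker, but 41 with no pool block, 29 with the correlation of 0.0844 and 1 with pool means without the marker term; all 41 and all 29 genes were among the 220, but 120 of the 282 (pool means with the marker) and 148 of the 175 (no filter) were. It ranged from 0 to 75 on leaving out pools or arrays: 20 without either CD34 pool, 0 without either Mts24 pool, and 5, 75, 8 and 6 without a CD34 negative, CD34 positive, Mts24 negative or Mts24 positive array of either genotype. Leaving out data leaves fewer residual degrees of freedom. The CD34 count of 2542 was 2359 to 2993 and the Mts24 count of 2448 was 2221 to 2964 over the settings that keep all arrays. With data left out, the CD34 count ranged from 1154 to 2280: 1154 without the K14Snail and 1200 without the wild type CD34 negative array, 1422 without either Mts24 pool and 1697 without the K14Snail CD34 pool. The Mts24 count then ranged from 0 without either Mts24 pool to 2897 without either CD34 positive array, and was 808 and 979 without the wild type, 661 and 987 without the K14Snail Mts24 negative and positive arrays. The difference between sorts gave 232 with the pool as a fixed block and ranged from 0 without either Mts24 pool to 830 without the K14Snail CD34 positive array; it was 744 without the K14Snail CD34 pool, 14 and 32 without the wild type or K14Snail CD34 negative array, 146 and 129 without the wild type, and 57 and 63 without the K14Snail Mts24 negative and positive arrays. The interaction gave 4 genes with the correlation of 0.0844; it was not run with data left out, where a left-out pool leaves no residual degrees of freedom. Lists past camera fell to 0 in all 5 comparisons with an estimated correlation, a setting that could hardly call a list with 3 or 2 residual degrees of freedom. For CD34 the bulge list, with 21 of 21 genes higher, had adjusted p = 0.402 in that camera rerun. The inflammatory cytokine list, with an estimated correlation of -0.039, under the preset 0.01, went from 0.0357 to 0.402. Other lists had estimates far above 0.01 in the main fit. These were 0.95 for cell cycle, 0.88 for myeloid, 0.82 for suprabasal and 0.61 for interferon response genes. Their p-values at the preset correlation are likely too small. With fry 0 lists passed for genotype, 8 for CD34 (hair shaft and p53 targets among them, which camera did not call), 3 for Mts24, 0 for the difference and 0 for the interaction. No filter gave 11 for genotype. At a threshold of 0.58 the single K14Snail against wild type counts were 359 in CD34 negative, 1230 in CD34 positive, 369 in Mts24 negative and 758 in Mts24 positive cells, and the positive against negative counts 2284 and 2339 for CD34 and 2094 and 2218 for Mts24 in wild type and K14Snail; a lower threshold admits more genes by construction. No result reversed. Of 240 results for named genes, 18 lost their call with no pool block, 21 with the correlation of 0.0844 and 165 without either Mts24 pool. Except where the construction shows it, the cause was not tested.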

Other observations

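The tests of the Mts24 profile given here, and the genes named beyond the rule, were chosen only after the values were seen. The list tests with camera had been fixed before. Of the 29 genes that pass for genotype at a pool correlation of 0.0844, the inflammatory caspases Casp1 (1.34) and Casp4 (1.21), the epithelial factor Ehf (1.26), the proton pump gene Atp12a (1.22), the complement inhibitor Serping1 (1.17), the interferon-induced Gbp7 (0.75) and Ube2l6 (0.75) and the angiogenic factor Vegfa (0.70) were higher in K14Snail cells. Limch1 (-0.92), Zdhhc23 (-0.92), the metallothionein Mt4 (-0.90), the transporter Abcc3 (-0.82), Cenpv (-0.78) and Hook1 (-0.73) were lower.

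Single members of lists that did not pass as groups separated the sorted cells. For CD34 the wound keratin Krt6a rose by 3.95, the melanocyte factor Mitf by 2.75, the hair factor Hoxc13 by 2.60 and the Notch effector Hey1 by 2.36, while Ascl2, a Wnt target, was at -1.85, and 5 of 17 p53 targets fell, such as Plk2 (-1.69), Sesn2 (-1.30) and Fas (-1.15), with Sesn1 higher (0.61). For Mts24 the chemokine Ccl2 rose by 3.03, Snai2 by 2.03 and Egr2 by 1.99, while the pigment genes Dct (-3.12) and Tyrp1 (-2.75) and the intermediate filament gene Vim (-2.18) were lower, with Mitf higher (1.07); 6 of 17 p53 targets fell, such as Mdm2 (-0.73), with Sesn1 higher (0.71), and Hey1 rose by 1.06. Of these lists the p53 targets had an adjusted p of 0.0875 for CD34 and 0.440 for Mts24 (limma's camera), and melanocyte genes 0.666 and 0.119.

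A further pattern concerned the Mts24 profile in the K14Snail CD34 positive array. From the Mts24 arrays alone, 336 genes were at least 2-fold higher and 306 lower in the positive fraction in both genotypes. The higher genes had a median of 0.47 in the K14Snail CD34 positive array against wild type, outside the -0.02 to 0.05 of 2000 random lists, and the lower genes -0.48. In CD34 negative cells the medians were smaller, 0.11 and -0.14. They also lay outside their random ranges, -0.02 to 0.02 and -0.02 to 0.03, so the pattern was not confined to CD34 positive cells. Without the cell cycle and DNA repair lists the higher genes had a median of 0.42, but this removed 18 of the 336 genes, so cell cycle genes outside the lists could still carry the shift. Correlations of whole arrays do not decide, since the pair of the same genotype was the higher: across genes, which are not independent replicates, the K14Snail and wild type CD34 positive arrays had r of 0.908 and 0.931 with the wild type and 0.927 and 0.8997 with the K14Snail Mts24 positive array. In the same pair of CD34 positive arrays upper follicle genes had a median of 0.61, with 9 of 10 above 0, while Plet1 was at 11.74 in K14Snail and 11.82 in wild type. A sort that took in more Mts24 positive cells stays open, and the pattern rests on 1 array per genotype.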
